A study of Mus musculus with 10 samples.

How the data were processed

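The series held 10 RNA-seq libraries of mouse microglia, all from cells that received EPZ-6438, an inhibitor of the histone H3K27 methyltransferase EZH2, at 10 uM. Primary microglia came from pooled brains of newborn ICR mice and were shaken off mixed glial cultures, per the labels' protocols. BV2 is an immortalised mouse microglial line. Cells were collected after 4 h with or without lipopolysaccharide (LPS), a bacterial cell wall component that activates Toll-like receptor 4, at 10 ng/ml. The groups were primary microglia with the inhibitor (PM_EPZ, n = 3), primary microglia with the inhibitor and LPS (PM_EPZ_LPS, n = 3), BV2 cells with the inhibitor (BV2_EPZ, n = 2) and BV2 cells with the inhibitor and LPS (BV2_EPZ_LPS, n = 2). Samples without the inhibitor were not analysed here, so each comparison describes cells under the inhibitor and none measures the inhibitor's own effect. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

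Libraries were made after ribosomal RNA removal with a directional kit and sequenced as read pairs, per the labels' protocols. Reads were processed with CASAVA 1.8.2, Trimmomatic 0.33 and STAR 2.5.1 on the mm10 build, per the submitters' processing notes, which also name DESeq2 without a version. The deposited files hold whole-number read counts per gene symbol in the layout of the STAR gene counter, with an unstranded column and 1 column per strand. The gene annotation behind these counts is not given in the sources used here. The column for the reverse strand was used because the kit marks the strand and this column held nearly all stranded gene reads. Between 0.682% and 2.21% of stranded gene reads lay on the other strand.

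Entries that name no gene (unmapped, multimapping, no feature, ambiguous) were left out of library sizes and tests, and held 70.4% to 79.5% of all reads. Multimapping reads made up 7.64% to 11.8%, so genes with near-identical copies (the Ifit, Oas, Gbp, Slfn, Irgm and H2 families, and Ccl2 with Ccl12) have uncertain counts. Gene counts per library ran from 2.75 to 3.68 M (1e6), with a median of 2.88 M, and 11657 to 14838 genes had a read. The precursor of ribosomal RNA, Rn45s, took 15.7% to 51.7% of gene counts. A count of 0 in a library allows up to 3 counts, or 0.814 to 1.09 CPM. Intervals and such limits cover counting error only.

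Replicates differed by more than sampling noise (chi-square over degrees of freedom of at least 1.52), so each library was counted once. Same-numbered primary libraries did not deviate together in each pair (correlations of deviations 0.200, -0.108 and 0.231), so the numbers were not taken to pair the samples. PM_EPZ replicates 1 and 2 deviated with PM_EPZ_LPS replicate 1 (0.200 and 0.166). PM_EPZ replicate 3 deviated with PM_EPZ_LPS replicates 2 and 3 (0.232 and 0.231). The other primary pairs lay between -0.345 and -0.108. This split was not balanced between the groups with and without LPS, and its cause was not tested. Deviations from a group's mean sum to 0, so these correlations depend on each other and are not separate observations of the split.

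Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust moderation, TMM normalization, the filterByExpr filter (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment. Adjusted p-values of genes are from this test, and a gene was called at an adjusted p under 0.05. The response to LPS was fitted in primary microglia (6 libraries) and in BV2 cells (4 libraries) separately. The difference of the responses and the difference between the cells without LPS came from a fit of all 10 libraries with 4 groups. Levels are CPM on TMM-scaled library sizes, as mean ± SD, and log2 fold changes are given ± SE. Where a group was at 0 in all its libraries the fold is a lower bound against 3 counts over the group. With 1 to 3 counts in a group the ratio is given with its 95% counting interval.

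The 34 gene lists, the comparisons, the tests and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison. A list call says that its genes ranked above or below the other genes. List members were also counted with p-values adjusted over the list alone, and a list's median is given also with members at 0 in a group at their bound and those with 1 to 3 counts at the ratio of their means. With a correlation estimated for each list, 7 of the 13 list calls in primary microglia, 3 of 10 in BV2 cells, 7 of 13 for the difference of responses and 3 of 11 between the cells held. The list of mitochondrial mRNAs had 0 genes in the files. Acod1 is listed there under its older symbol Irg1.

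The genes named are, for each comparison, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups (this last condition not for the difference of responses), without unnamed gene models, microRNAs and small nucleolar RNAs. Added to these are key genes given whatever their result (Ezh2, Ezh1, Eed, Suz12, Kdm6a, Kdm6b, Tnf, Il1b, Il6, Il10, Nos2, Ccl2, Cxcl10, Ifnb1, Arg1, Irf1, Irf8, P2ry12, Tmem119 and Cx3cr1) and, from each list, up to 4 called members with the largest change and up to 2 uncalled members with the highest level. Some genes that these rules name are not reported here. Positions are from a GRCm38 (mm10) annotation, in which 24286 of the 24411 gene symbols of the files were found (99.5%).

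The procedure was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 69 and 95 of them in primary microglia, 75 and 98 in BV2 cells, 33 and 78 for the difference of responses, and 56 and 93 between the cells. False calls were 16 of 210, 7 of 202, 7 of 133 and 11 of 189. The totals include true calls among NF-kB pathway list members, which were also raised 2-fold (34 members, or 31 in BV2 cells). Apart from the changed genes, each simulated gene had 1 mean level in all libraries. The simulated cells thus started alike, whereas 74.1% of tested genes differed between the real cells without LPS. The figures for the difference of responses and between the cells may therefore not hold for genes at unlike levels. Alternatives were another normalization, no or a stricter filter on low counts, unstranded counts, structural RNAs removed, limma-voom, DESeq2 1.42.0, a shared or separate fit, the replicate number as a block, other list tests and leaving out each library in turn. Removing each library's trend on transcript length and GC content, and keeping a single primary library with LPS, were chosen after seeing the data. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.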

Results

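The series asks how microglia, the resident macrophages of the brain, express inflammation genes under an EZH2 inhibitor. RNA was sequenced from primary mouse microglia treated with EPZ-6438 without LPS (n = 3) or with LPS (n = 3), and from the BV2 microglial line treated in the same 2 ways (n = 2 each). Gene counts per library were 3.11, 2.96 and 2.75 M (1e6) in primary microglia without LPS and 3.68, 2.77 and 3.13 M with LPS. They were 2.81 and 2.78 M in BV2 cells without LPS and 2.78 and 3.15 M with LPS. Rn45s, the ribosomal RNA precursor, took 50.3%, 51.7% and 40.9% of gene counts in the primary libraries without LPS and 43.7%, 15.7% and 16.0% in those with LPS. In BV2 libraries its share was 26.997% and 30.1% without LPS and 28.6% and 27.2% with LPS. Without 5 abundant structural genes, 1.22, 1.11 and 1.33 M counts were left in the primary libraries without LPS and 1.65, 2.05 and 2.36 M in those with LPS. Log2 levels of replicates correlated across genes at 0.961 to 0.988, and those of libraries from different groups at 0.493 to 0.972. Among primary libraries with LPS, replicate 1 stood apart (0.961 and 0.963 with the others, which correlated at 0.980). Genes are not independent replicates in these correlations.

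The first comparison asked which genes LPS changed in primary microglia held under the inhibitor. Cxcl10, a chemokine that draws T cells (chromosome 5, 92346638 to 92348889), went from 0 counts to 477 ± 134 CPM, at least 1311-fold higher (n = 3 per group, adjusted p = 2.01e-05). Rsad2, an antiviral enzyme (chromosome 12, 26442743 to 26456452), rose from 0.832 ± 0.423 to 3918 ± 435 CPM (log2 fold change 12.14 ± 0.22, adjusted p = 4.31e-18). Irg1, which makes the metabolite itaconate (chromosome 14, 103047012 to 103056573), rose from 2.46 ± 0.475 to 5225 ± 228 CPM (log2 fold change 11.02 ± 0.18, adjusted p = 1.98e-18). Il1b, which encodes the cytokine interleukin-1 beta (chromosome 2, 129364569 to 129371164), rose from 2.502 ± 0.773 to 4321 ± 294 CPM (log2 fold change 10.74 ± 0.19, adjusted p = 4.20e-18). In all, 4178 of 10664 tested genes were called (39.2%), of which 2285 rose and 1893 fell, and 1103 rose and 894 fell by at least 2-fold. The groups did not overlap for 5228 genes (49.0%), where chance gives 10%. The biological coefficient of variation was 13.1%.

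The other genes among the largest rises were Ifit1, an interferon-induced RNA-binding protein, with a ratio of 10793 (95% counting interval 1937 to 426322), and Oasl1, with a ratio of 3640 (653 to 143809). Il12b, a subunit of interleukins 12 and 23, went from 0 to 279 ± 4.68 CPM, at least 787-fold higher. Il27 was at least 382-fold higher, the GTPase gene Iigp1 at least 334-fold and the protease inhibitor gene Serpina3g at least 280.5-fold. Gbp5, a guanylate-binding protein, rose from 0.689 ± 0.704 to 2423 ± 111 CPM. The largest falls were led by Cnr2, the cannabinoid receptor 2 gene (chromosome 4, 135895189 to 135920219), from 14.0 ± 4.35 CPM to 0 counts, at least 46.3-fold lower. Arhgap19, a GTPase regulator (chromosome 19, 41766588 to 41802084), fell from 88.5 ± 5.61 to 2.90 ± 0.863 CPM (log2 fold change -4.90 ± 0.20, adjusted p = 1.65e-13). The orphan receptor gene Gpr157 fell from 107 ± 2.57 to 4.46 ± 0.815 CPM, the transcription factor gene Lyl1 from 30.7 ± 1.29 to 1.29 ± 0.920 CPM and the ubiquitin ligase component Fbxo32 from 58.7 ± 11.6 to 2.77 ± 1.02 CPM. Rasgrp3 (log2 fold change -4.31 ± 0.37) and the transporter gene Slco2b1 (-4.24 ± 0.44) fell as well. Klhl6, Rab3il1 and Gpr183, an oxysterol receptor, were lower with control-to-LPS ratios of 35.6 (9.45 to 300.8), 32.7 (10.8 to 161.8) and 20.2 (6.56 to 101.4).

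Of the cytokine list, 20 of 23 tested members rose and 0 fell (median log2 fold change 6.96, or 4.92 with members at their bound, camera adjusted p = 1.80e-42). Tnf rose from 4.56 ± 0.972 to 2941 ± 160 CPM and Il6 from 0.476 ± 0.416 to 638 ± 71.4 CPM (log2 fold changes 9.31 ± 0.17 and 10.28 ± 0.26, adjusted p = 4.31e-18 and 2.15e-16). Ifnb1, interferon beta, went from 0 to 10.7 ± 0.539 CPM, at least 30.2-fold higher (adjusted p = 8.16e-08). Il10 had too few counts to be tested. Chemokines rose in 16 of 19 and fell in 1 (median 8.46, or 8.22 at the bound, adjusted p = 1.35e-53), with Ccl2 from 2.45 ± 0.833 to 750 ± 75.0 CPM and Ccl4 from 1.62 ± 0.611 to 1983 ± 181 CPM. All 48 tested interferon-stimulated genes rose (median 6.84, or 6.83 at the bound, adjusted p = 2.70e-176). NF-kB pathway genes and feedback inhibitors rose in 33 of 34 (median 3.32, adjusted p = 2.81e-49), including Icam1 (5.87 ± 0.15) and Traf1 (7.44 ± 0.23). The exception, Dusp1, was at 0.03 ± 0.19 (adjusted p = 0.907). Classical activation genes rose in 20 of 20 (median 4.34, adjusted p = 1.54e-60), with the receptor gene Cd40 from 0.583 ± 0.174 to 857 ± 34.2 CPM. Nos2, the inducible nitric oxide synthase, had a ratio of 991 (177 to 39156, adjusted p = 2.55e-04). IRF and STAT factors rose in 9 of 13 and fell in 1 (median 2.04, adjusted p = 2.91e-13). Irf1 rose from 17.1 ± 2.99 to 746 ± 54.1 CPM, while Irf8 was at -0.22 ± 0.13 (adjusted p = 0.176). Antigen presentation genes rose in 17 of 17 (median 2.61, adjusted p = 2.01e-22), among them the transactivator Nlrc5 (4.77 ± 0.14) and the peptide transporter Tap1 (4.58 ± 0.14). In these 7 lists the counts adjusted over the list alone were the same. With an estimated correlation, their camera adjusted p ran from 0.00205 (NF-kB pathway genes) to 0.0260 (IRF and STAT factors). It was 0.00651 for interferon-stimulated genes and 0.0137 for cytokines.

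Toll-like receptor pathway genes rose in 13 of 27 and fell in 3 (median 0.56, adjusted p = 1.70e-04, and adjusted p = 0.0997 with an estimated correlation). Tlr2 rose from 101 ± 9.91 to 1567 ± 139 CPM and Cd14, the LPS co-receptor, from 266 ± 33.2 to 2841 ± 292 CPM. Inflammasome genes rose in 10 of 17 and fell in 1 (median 1.40, adjusted p = 2.43e-08, and adjusted p = 0.0570 with an estimated correlation), with Nlrp3 from 7.83 ± 1.44 to 508 ± 117 CPM. NRF2 targets rose in 12 of 17 (median 1.19, adjusted p = 2.43e-08, and adjusted p = 0.0997 with an estimated correlation), with the cystine transporter gene Slc7a11 from 39.6 ± 4.82 to 1008 ± 59.8 CPM. Complement genes rose in 8 of 14 (median 0.72, adjusted p = 7.95e-04, and adjusted p = 0.232 with an estimated correlation), with C3 from 52.6 ± 6.32 to 421 ± 40.9 CPM, whereas C1qa was at 0.06 ± 0.15 (adjusted p = 0.800). Glycolysis genes rose in 12 of 20 (median 0.66, adjusted p = 0.00688, and adjusted p = 0.232 with an estimated correlation), with the glucose transporter gene Slc2a1 from 25.3 ± 1.73 to 127 ± 4.30 CPM. Phagocytosis and Fc receptor genes rose in 12 of 25 and fell in 6, or 13 and 6 adjusted over the list alone (median 0.32, adjusted p = 0.0242, and adjusted p = 0.215 with an estimated correlation). In that list the lectin receptor gene Clec4e rose from 1.68 ± 0.924 to 707 ± 48.6 CPM.

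Of the homeostatic microglia genes, 5 of 30 rose and 14 fell (median -0.38, adjusted p = 0.392). The purinergic receptor gene P2ry12 fell from 5.34 ± 1.35 to 1.93 ± 0.405 CPM (adjusted p = 0.00600). Cx3cr1, the fractalkine receptor, was at 122 ± 10.0 and 113 ± 8.82 CPM (adjusted p = 0.493), and Tmem119 had too few counts to be tested. Alternative activation genes rose in 4 of 13 and fell in 1 (median 0.30, adjusted p = 0.206), and Arg1 was at 0.45 ± 0.33 (adjusted p = 0.304). Disease-associated microglia genes rose in 9 of 26 and fell in 7 (median 0.09, adjusted p = 0.760), with the growth factor gene Csf1 up by 2.51 ± 0.12 and Apoe at 0.21 ± 0.13 (adjusted p = 0.215). Matrix metalloproteinases and inhibitors rose in 7 of 16 and fell in 4 (median 0.49, adjusted p = 0.181, and 0.0204 with no low-count filter), led by Mmp13 (5.13 ± 0.18). LXR targets rose in 1 of 15 and fell in 6 (median -0.28, adjusted p = 0.206), where the cholesterol exporter gene Abca1 fell from 859 ± 17.2 to 423 ± 11.6 CPM. Cholesterol synthesis genes rose in 5 of 21 and fell in 3 (median -0.04, adjusted p = 0.900), cell cycle genes in 4 and 3 of 18 (-0.12, adjusted p = 0.788), and stress response genes of the unfolded protein pathway in 4 and 4 of 18 (-0.16, adjusted p = 0.911). Immediate early genes rose in 6 of 18 and fell in 2, or 6 and 3 adjusted over the list alone (median 0.43, adjusted p = 0.181), with Junb at 2.61 ± 0.15 and Fos at -1.72 ± 0.35.

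The target of the inhibitor, Ezh2 (chromosome 6, 47530274 to 47595270), was at 17.0 ± 0.715 CPM without LPS and 14.0 ± 2.29 CPM with LPS (log2 fold change -0.29 ± 0.21, adjusted p = 0.281). Its complex partner Eed was at 0.16 ± 0.19 (adjusted p = 0.538) and the H3K27 demethylase gene Kdm6b at 0.68 ± 0.27 (adjusted p = 0.0563, and 0.0129 without PM_EPZ_LPS replicate 2). Ezh1, the related methyltransferase, fell from 28.7 ± 5.37 to 17.5 ± 4.47 CPM (adjusted p = 0.00867), and the demethylase gene Kdm6a from 65.8 ± 5.15 to 47.0 ± 1.04 CPM (adjusted p = 0.00524). Suz12, another core subunit, rose from 36.8 ± 4.27 to 52.8 ± 8.04 CPM (adjusted p = 0.00989). Single libraries decided the Suz12 and Ezh1 calls (adjusted p = 0.0718 and 0.0574 without PM_EPZ_LPS replicate 3, 0.0607 for Suz12 without PM_EPZ replicate 3, and 0.0863 for Ezh1 without PM_EPZ replicate 1). Of the PRC2 and demethylase list 2 of 14 rose and 3 fell (median 0.14, mean 0.00, camera direction down, adjusted p = 0.811). PRC1 subunits rose in 5 of 17 and fell in 5 (median -0.25, adjusted p = 0.928), with Pcgf5 at 2.41 ± 0.18 and Cbx7 at -1.97 ± 0.34. Developmental regulators typical of Polycomb targets rose in 1 of 10 and fell in 3 (median -0.30, adjusted p = 0.592).

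Markers of other cell types were measured in the same libraries. Astrocyte markers rose in 1 of 14 and fell in 3 (median -0.21, adjusted p = 0.403), with Gfap, the astrocyte filament gene, at 659 ± 217 CPM without LPS and 674 ± 269 CPM with LPS. Oligodendrocyte lineage markers rose in 1 of 10 and fell in 1 (-0.35, adjusted p = 0.697), neuron markers rose in 2 of 7 (0.35, adjusted p = 0.842), endothelial and mural markers changed in 0 of 5 (-0.10, adjusted p = 0.788) and fibroblast markers fell in 1 of 11 (-0.47, adjusted p = 0.403). Neutrophil, monocyte and border macrophage markers had 4 tested genes, 0 of them called, and the only tested lymphocyte marker was Cd4 (-0.81 ± 0.29, adjusted p = 0.0372). The Cd4 call was lost without PM_EPZ replicate 1 (adjusted p = 0.0657) or 3 (0.166), and without PM_EPZ_LPS replicate 1 (0.0735), 2 (0.0752) or 3 (0.0548). Heat shock genes rose in 4 of 10 and fell in 1, or 4 and 2 adjusted over the list alone (median 0.26, adjusted p = 0.809). Called falls had longer transcripts (median 4403 bases) than called rises (3271.5) and genes not called (3469.5). The slope of a library's log2 levels on transcript length was 0.12, 0.11 and 0.01 per length doubling without LPS and 0.06, -0.18 and -0.13 with LPS.

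**Figure D1:**
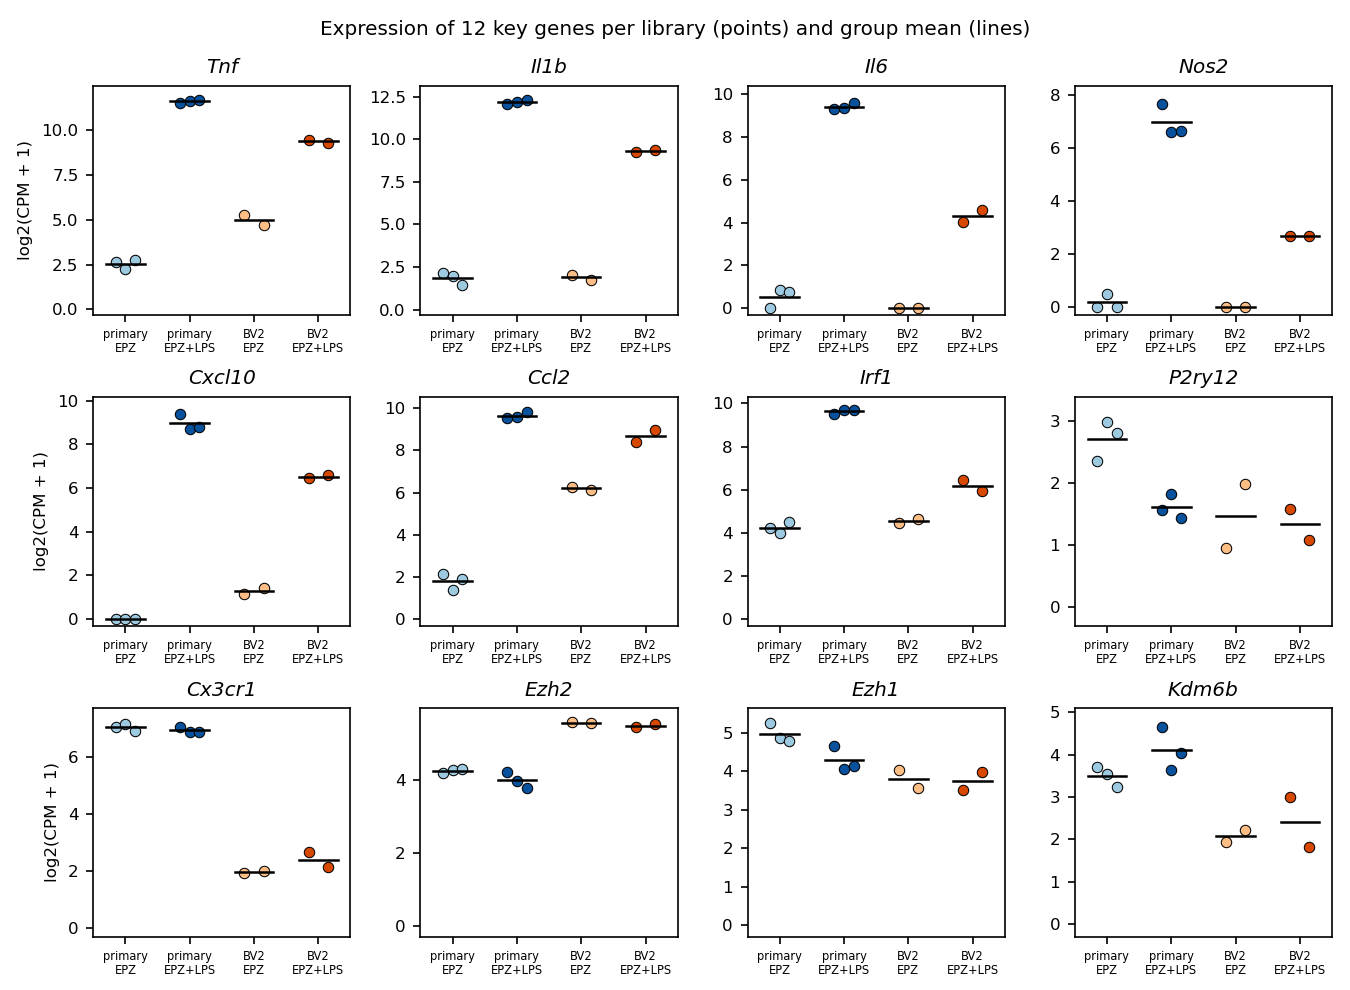
Levels of 12 key genes, as log2(CPM + 1), in each of the 10 libraries by group; points are libraries and lines group means. Tnf and Il1b lie higher with LPS in both kinds of cells, and Ezh2 lies higher in BV2 cells than in primary microglia.

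The second comparison asked the same of BV2 cells. Cxcl2, a neutrophil chemokine (chromosome 5, 90903899 to 90905938), went from 0 counts to 250 ± 27.5 CPM, at least 476-fold higher (n = 2 per group, adjusted p = 7.66e-09). Csf3, the granulocyte growth factor (chromosome 11, 98700183 to 98703631), went from 0 to 92.7 ± 4.22 CPM, at least 175-fold higher, and Il6 from 0 to 21.3 ± 6.40 CPM, at least 41.1-fold higher. Irg1 rose from 2.45 ± 0.361 to 725 ± 26.0 CPM and Il1b from 2.98 ± 0.581 to 710 ± 55.8 CPM (log2 fold changes 8.18 ± 0.20 and 7.87 ± 0.20, both with an adjusted p of 2.00e-10). In all, 485 of 9321 genes were called (5.20%), of which 344 rose and 141 fell, and 261 rose and 84 fell by at least 2-fold. The groups did not overlap for 3932 genes (42.2%), where chance gives 33.3%.

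The acute-phase gene Saa3 rose from 5.15 ± 1.53 to 650 ± 100.0 CPM and Il1a from 1.07 ± 0.558 to 223 ± 29.8 CPM. Lcn2, which binds bacterial siderophores, had a ratio of 320 (57.0 to 12677). The scavenger receptor gene Marco was at least 26.1-fold higher and Nos2 at least 11.4-fold higher, at 13.8 ± 0.0707 and 6.03 ± 0.0610 CPM with LPS. Tnf rose from 34.3 ± 8.54 to 751 ± 53.0 CPM (log2 fold change 4.45 ± 0.17, adjusted p = 6.97e-09) and Cxcl10 from 1.59 ± 0.338 to 103 ± 9.52 CPM (5.98 ± 0.27). Among falls, the chemokine receptor gene Cxcr4 (chromosome 1, 128588199 to 128592299) went from 27.5 ± 1.53 to 2.11 ± 0.721 CPM (log2 fold change -3.70 ± 0.33, adjusted p = 1.35e-05). Thrombomodulin, Thbd, fell from 13.2 ± 1.49 to 1.04 ± 0.116 CPM and Gpr183 from 54.9 ± 12.4 to 6.35 ± 0.513 CPM. Tmem86a (-2.79 ± 0.49), Zfp395 (-2.44 ± 0.47) and Lbh (-2.17 ± 0.34) fell too. Sgsm2, Tsc22d3, Klhl6 and Frmd4b fell with adjusted p = 0.0203, 0.0122, 0.0196 and 0.0146, and each lost its call without at least 1 library (without BV2_EPZ replicate 1, adjusted p = 0.0744 for Sgsm2 and 0.0684 for Tsc22d3; without BV2_EPZ replicate 2, 0.207 for Klhl6 and 0.104 for Frmd4b; without BV2_EPZ_LPS replicate 2, 0.131 for Sgsm2, 0.0877 for Klhl6 and 0.0609 for Frmd4b).

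NF-kB pathway genes rose in 27 of 32 (30 adjusted over the list alone, median 1.93, adjusted p = 5.43e-90), with Tnfaip2 from 84.2 ± 11.2 to 1184 ± 209 CPM. Classical activation genes rose in 14 of 15 (median 3.62, or 3.51 at the bound, adjusted p = 3.51e-104) and cytokines in 8 of 11 (9 adjusted over the list alone, median 1.54, adjusted p = 9.19e-68). With an estimated correlation, the camera adjusted p was 0.0467 for each of the NF-kB, classical activation and cytokine lists. Chemokines rose in 8 of 11 (10 adjusted over the list alone, median 2.54, adjusted p = 3.16e-66, and adjusted p = 0.116 with an estimated correlation), with Ccl2 from 79.8 ± 3.51 to 467 ± 134 CPM. Interferon-stimulated genes rose in 13 of 25 (17 adjusted over the list alone, median 1.41, adjusted p = 3.96e-16, and adjusted p = 0.148 with an estimated correlation). In that list Ifit1 rose from 1.23 ± 0.180 to 15.2 ± 2.45 CPM, and Oas1a was at 0.24 ± 0.22 (adjusted p = 0.737). Immediate early genes rose in 8 of 11 (10 adjusted over the list alone, median 1.21, adjusted p = 1.09e-15, and adjusted p = 0.148 with an estimated correlation), with Btg2 at 2.29 ± 0.22 and Maff at 2.33 ± 0.29. NRF2 targets rose in 4 of 16 (median 0.18, adjusted p = 4.59e-05, and adjusted p = 0.148 with an estimated correlation). Toll-like receptor pathway genes rose in 5 of 23 and fell in 1, or 6 and 3 adjusted over the list alone (median 0.17, adjusted p = 3.94e-04, and adjusted p = 0.164 with an estimated correlation). Inflammasome genes rose in 3 of 16 and fell in 1, with a median of -0.11 against a test that pointed up (adjusted p = 3.36e-05, and adjusted p = 0.148 with an estimated correlation). Antigen presentation genes rose in 3 of 18 (median 0.25, adjusted p = 0.0405, and adjusted p = 0.304 with an estimated correlation), and this call was lost without BV2_EPZ replicate 2 (adjusted p = 0.0973) or BV2_EPZ_LPS replicate 1 (adjusted p = 0.108). The inflammasome call was lost without BV2_EPZ_LPS replicate 2 (adjusted p = 0.0613).

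IRF and STAT factors rose in 3 of 13 and fell in 1, or 4 and 3 adjusted over the list alone (median 0.20, adjusted p = 0.271). Irf1 rose from 24.5 ± 2.61 to 81.7 ± 19.3 CPM. PRC2 and demethylase genes were called in 0 of 13 (median -0.02, adjusted p = 0.901). Ezh2 was at 51.1 ± 0.360 CPM without LPS and 49.3 ± 3.05 CPM with LPS (log2 fold change -0.05 ± 0.16, adjusted p = 0.948), Suz12 at -0.05 ± 0.25, Eed at 0.02 ± 0.20, Ezh1 at -0.02 ± 0.28, Kdm6a at -0.15 ± 0.16 and Kdm6b at 0.56 ± 0.51. Irf8 was at -0.51 ± 0.19 (adjusted p = 0.193), Tmem119 at -0.55 ± 0.26 and Cx3cr1 at 0.60 ± 0.44, while Arg1, Ifnb1, Il10 and P2ry12 had too few counts to be tested. Homeostatic microglia genes rose in 3 of 25 and fell in 1, or 3 and 7 adjusted over the list alone (median -0.21, adjusted p = 0.491). Cell cycle genes were called in 0 of 40 (median -0.10, adjusted p = 0.324), PRC1 subunits in 0 of 17 (0.05, 0.541), alternative activation genes in 0 of 10 (-0.29, 0.247) and heat shock genes in 0 of 9 (-0.02, 0.728). Metalloproteinase genes rose in 2 of 8 and fell in 1, or 4 and 2 over the list alone (median 0.54, adjusted p = 0.207), LXR targets in 1 and 2 of 12, or 1 and 5 (-0.15, 0.129), phagocytosis genes in 4 and 2 of 21, or 4 and 3 (-0.03, 0.207), complement genes in 2 and 0 of 11, or 2 and 1 (-0.03, 0.443), and stress response genes of the unfolded protein pathway in 2 and 0 of 16, or 3 and 1 (0.05, 0.207). Glycolysis genes rose in 2 of 20 (median 0.03, adjusted p = 0.541), cholesterol synthesis genes in 1 of 20 (0.18, 0.181, and 0.0465 with no low-count filter) and disease-associated microglia genes in 1 of 24 (-0.02, 0.842). Without BV2_EPZ_LPS replicate 2 the glycolysis and cholesterol synthesis lists and Suz12 passed (adjusted p = 0.0418, 0.0273 and 0.0407). Of 3 developmental regulators 1 fell, Pax3 (adjusted p = 0.0489), and that call was lost without any of the 4 libraries (0.224 without BV2_EPZ replicate 1, 0.124 without BV2_EPZ replicate 2, 0.101 without BV2_EPZ_LPS replicate 1 and 0.0622 without BV2_EPZ_LPS replicate 2). Markers of other cell types had 8 tested genes with 0 calls, and over the list alone 1 of 3 neutrophil, monocyte and border macrophage markers was lower. Leaving out BV2_EPZ_LPS replicate 1 moved the calls to 800 (547 rose, 253 fell), and the falls were 82 without BV2_EPZ replicate 1 and 89 without BV2_EPZ replicate 2. DESeq2 called 318 genes (261 rose, 57 fell), and 774 were called with each library's length and GC trend removed (476 rose, 298 fell).

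**Figure D2:**
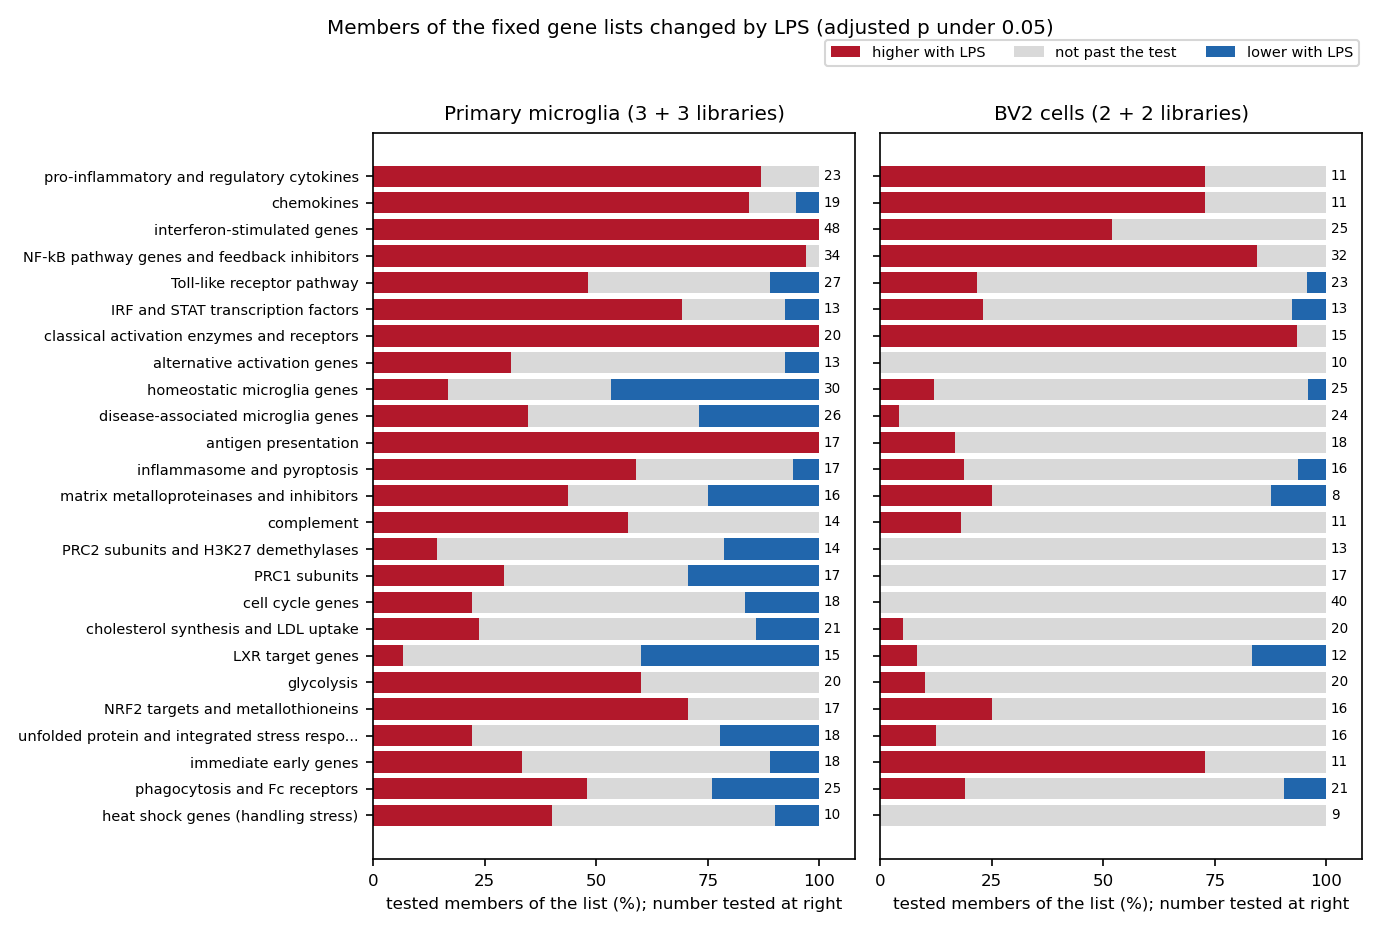
Percent of tested members of 25 gene lists that were higher, lower or not past the test with LPS, in primary microglia and in BV2 cells, with the number tested at the right of each bar. All 48 interferon-stimulated genes tested in primary microglia were higher, and 13 of 25 in BV2 cells.

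The third comparison tested whether the responses differed between primary microglia and BV2 cells. Of the interferon-stimulated genes, 34 of 48 responded more in primary microglia and 0 less (40 adjusted over the list alone, camera adjusted p = 6.81e-46). Rsad2 went from 0.886 ± 0.451 to 4207 ± 464 CPM in primary microglia (n = 3) and from 5.31 ± 0.898 to 30.1 ± 6.46 CPM in BV2 cells (n = 2), a difference of log2 fold changes of 9.65 ± 0.51 (adjusted p = 6.02e-14). Ifit2, another interferon-induced RNA-binding protein, went from 8.56 to 2614 CPM in primary microglia and from 3.84 to 4.44 CPM in BV2 cells (difference 8.004 ± 0.54, adjusted p = 1.25e-11). Oasl1 (chromosome 5, 114923143 to 114937911) reached 460 CPM against 36.5 CPM with LPS, and Ifit1 1366 CPM against 13.5 CPM. Ifi47, an interferon-induced GTPase, differed by 8.24 ± 0.95 and the transcription factor gene Irf7 by 7.59 ± 0.42. In all, 1418 of 11626 genes differed, 1006 with a higher and 412 with a lower log2 response in primary microglia, and 701 and 311 by at least 2-fold. With structural RNAs removed before normalization the split was 809 and 536, with a median shift of -0.10 over all genes. Without PM_EPZ_LPS replicate 1 it was 1048 and 876, and the lower count was 271 without BV2_EPZ replicate 1 and 273 without BV2_EPZ replicate 2.

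Antigen presentation genes responded more in primary microglia in 17 of 18 (adjusted p = 2.41e-35). Nlrc5 went from 16.0 to 444 CPM there and from 54.9 to 64.7 CPM in BV2 cells (difference 4.55 ± 0.22). Of IRF and STAT factors, 8 of 13 responded more (adjusted p = 1.32e-19), Irf1 by 3.75 ± 0.25. Chemokines did so in 8 of 20 and, adjusted over the list alone, 8 more and 1 less (adjusted p = 2.66e-13). Ccl2 differed by 5.72 ± 0.30 and Ccl5, a chemokine for T cells, by 7.73 ± 0.78. For NF-kB pathway genes it was 16 of 34, or 19 more and 1 less over the list alone (adjusted p = 1.27e-12), and for NRF2 targets 9 of 18 (10 over the list alone, adjusted p = 7.12e-07). Classical activation genes split into 11 more and 4 less of 21 (adjusted p = 7.29e-09). With an estimated correlation, the camera adjusted p was 0.00403 for interferon-stimulated and antigen presentation genes and 0.0108 for NF-kB pathway genes. It was 0.0243 for IRF and STAT factors, 0.0340 for chemokines, 0.0376 for classical activation genes and 0.0440 for NRF2 targets. Cytokines split into 7 more and 1 less of 24, or 10 and 2 over the list alone (adjusted p = 2.04e-04, and adjusted p = 0.0775 with an estimated correlation). Tnf differed by 4.91 ± 0.26 and Il1b by 2.92 ± 0.45 (adjusted p = 6.35e-14 and 1.84e-05), while Il6, Nos2 and Ifnb1 were at 0 in BV2 controls and their differences had SEs too large to read. Ccl2 and Tnf were already higher in BV2 cells without LPS, so their larger log2 responses started from lower levels in primary microglia. Inflammasome genes responded more in 9 of 19, or 9 more and 1 less over the list alone (adjusted p = 3.48e-06, and adjusted p = 0.0522 with an estimated correlation), Toll-like receptor pathway genes in 8 of 27 with 1 less, or 10 and 1 over the list alone (adjusted p = 3.20e-05, and adjusted p = 0.0522 with an estimated correlation) and glycolysis genes in 9 of 20, or 11 over the list alone (adjusted p = 3.19e-05, and adjusted p = 0.0819 with an estimated correlation). Complement genes did so in 6 of 15 (adjusted p = 0.0151, and adjusted p = 0.292 with an estimated correlation), and phagocytosis genes split into 6 and 6 of 25, or 9 and 6 over the list alone (adjusted p = 0.0301, and adjusted p = 0.101 with an estimated correlation). The phagocytosis call was lost without PM_EPZ replicate 2 (adjusted p = 0.0688), PM_EPZ_LPS replicate 1 (0.106) or BV2_EPZ_LPS replicate 2 (0.0564), and the 15 PRC2 and demethylase genes gave 0 calls (adjusted p = 0.952). Among these, Ezh2 differed by -0.20 ± 0.26 (adjusted p = 0.783), Suz12 by 0.63 ± 0.31 (0.246), Ezh1 by -0.66 ± 0.36 (0.296), Eed by 0.19 ± 0.27 (0.822), Kdm6a by -0.29 ± 0.21 (0.474) and Kdm6b by 0.17 ± 0.62 (1.00). Suz12 passed without BV2_EPZ_LPS replicate 2 (adjusted p = 0.00448) and Ezh1 without PM_EPZ_LPS replicate 1 (0.0420). Differences for microglial genes were 0.34 ± 0.22 for Irf8, -0.67 ± 0.40 for Cx3cr1, -1.12 ± 0.80 for P2ry12, 0.23 ± 0.56 for Tmem119 and 1.19 ± 0.71 for Arg1, with adjusted p = 0.419, 0.387, 0.474, 0.9497 and 0.356. Of the remaining lists, homeostatic microglia genes split into 4 more and 4 less of 32, or 5 and 5 over the list alone (adjusted p = 0.753), disease-associated genes into 7 and 3 of 26 (0.283), immediate early genes into 2 and 4 of 18, or 3 and 5 over the list alone (0.152), alternative activation genes into 2 and 1 of 14 (0.426), PRC1 subunits into 2 and 1 of 19 (0.952) and stress response genes of the unfolded protein pathway into 2 and 1 of 18 (0.753). Cell cycle genes gave 2 more of 40 (0.554), cholesterol synthesis genes 1 more of 21 (0.498), LXR targets 1 and 1 of 15 (0.835), heat shock genes 1 more of 10 (0.586) and oligodendrocyte markers 1 more of 10 (0.952). There were 0 calls among 16 metalloproteinase genes, 12 developmental regulators, the astrocyte, neuron, endothelial and fibroblast markers, and the only tested lymphocyte marker. Of 4 neutrophil, monocyte and border macrophage markers, 1 responded more, or 2 over the list alone.

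Among lower log2 responses in primary microglia was Cnr2, which went from 14.9 ± 4.63 CPM to 0 counts in primary microglia and from 9.41 to 3.09 CPM in BV2 cells, and the size of its difference is not given because a group was at 0. Arhgap19 went from 94.2 to 3.11 CPM in primary microglia and from 82.6 to 56.7 CPM in BV2 cells (difference -4.35 ± 0.27, adjusted p = 1.49e-12). Il16, a T cell attractant (chromosome 7, 83642819 to 83746028), went from 10.4 to 0.687 CPM and from 21.8 to 20.4 CPM (-3.81 ± 0.51). Gdf15, a stress-induced growth factor (chromosome 8, 70629393 to 70632470), was at 1.13 and 1.22 CPM in primary microglia, and rose to 10.4 CPM from a single count in BV2 cells. Gadd45a, a DNA damage response gene, was at 11.4 and 12.4 CPM in primary microglia and went from 0.477 to 9.40 CPM in BV2 cells. Marco went from 33.9 to 402 CPM in primary microglia and from 0 to 12.3 CPM in BV2 cells, and its difference was lost without BV2_EPZ replicate 1 or 2 (adjusted p = 0.133 and 0.113).

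Across the 8620 genes tested in both kinds of cells, the log2 responses correlated with Pearson's r = 0.646 and a Spearman coefficient of 0.473, described without a p because genes are not independent replicates. With no low-count filter Pearson's r was 0.367 over 12501 genes. The fits share no library. Both kinds of cells raised 292 genes, where independent lists would share 75.5, and lowered 102, where 22.97 would be shared. Another 8 genes rose in primary microglia and fell in BV2 cells (30.0 by chance), and 3 did the reverse (57.8 by chance). Of the genes BV2 cells raised, 88.0% also rose in primary microglia, and of those they lowered, 77.3% fell. Over genes called in both kinds of cells, the 11 of opposite sign included, the median size of the log2 fold change was 2.33 in primary microglia and 1.33 in BV2 cells.

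**Figure D3:**
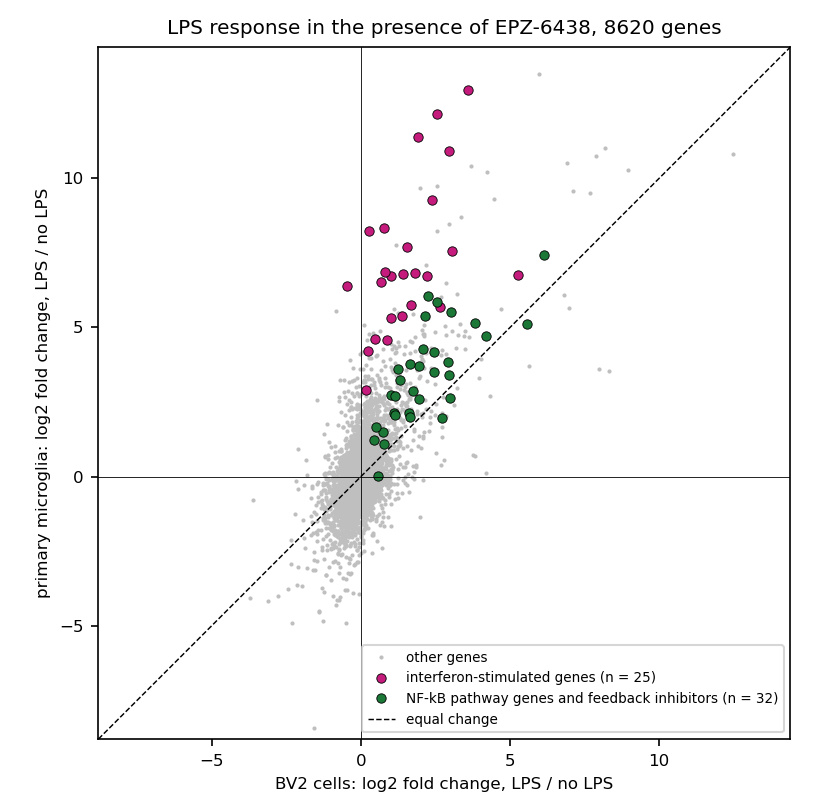
Fitted log2 fold change with LPS in BV2 cells (x axis) against primary microglia (y axis) for the 8620 genes tested in both, with 25 interferon-stimulated and 32 NF-kB pathway genes coloured and a dashed line of equal change. Across these genes Pearson's r was 0.646, and 0.367 over 12501 genes with no low-count filter.

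The last comparison described the cells without LPS. Gfap (chromosome 11, 102887336 to 102897200) was at 701 ± 231 CPM in primary microglia (n = 3) and 0 counts in BV2 cells (n = 2), at least 1434-fold higher (adjusted p = 5.51e-04). The neural proteoglycan gene Ncan was at least 810-fold higher, the metalloproteinase inhibitor gene Timp3 (chromosome 10, 86300412 to 86349505) at least 689-fold and fibronectin, Fn1, at least 621-fold. BV2 cells had more of the lysosomal protease gene Ctsk (chromosome 3, 95499210 to 95509387), at 2414 ± 79.4 against 8.10 ± 1.24 CPM (log2 difference -8.22 ± 0.18, adjusted p = 2.62e-23). In all, 8611 of 11626 genes differed (74.1%), 4829 higher and 3782 lower in primary microglia, and libraries did not overlap for 9783 (84.1%, chance 20%). Strain, age and culture went with the kind of cell.

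Cell cycle genes were lower in primary microglia in 40 of 40 (median -4.02, adjusted p = 5.67e-37), with the mitotic kinase gene Aurka at 1.85 ± 0.930 against 188 ± 18.8 CPM. Homeostatic microglia genes were higher in 22 of 32 and lower in 5 (median 1.36, adjusted p = 8.13e-05). Cx3cr1 (chromosome 9, 120048683 to 120068296) was at 130 ± 10.7 against 2.89 ± 0.118 CPM, Tmem119 at 2.51 ± 0.287 against 15.7 ± 3.44 CPM, and P2ry12 at 5.68 ± 1.44 against 1.95 ± 1.44 CPM (adjusted p = 0.00643, and 0.154 without BV2_EPZ replicate 1). Metalloproteinases and inhibitors were higher in 13 of 16 (median 3.29, adjusted p = 5.74e-06). With an estimated correlation, the camera adjusted p was 1.50e-04 for cell cycle genes and 0.0256 for both homeostatic microglia genes and metalloproteinases. Ezh2 was lower in primary microglia, at 18.1 ± 0.756 against 46.5 ± 0.366 CPM (log2 difference -1.36 ± 0.18, adjusted p = 2.17e-07), as were Suz12 (-1.21 ± 0.22) and Eed (-1.09 ± 0.20), while Ezh1 was higher (1.22 ± 0.25). Over that list 7 of 15 were higher and 7 lower (median 0.11, adjusted p = 0.754). Kdm6b was higher in primary microglia (1.67 ± 0.43, adjusted p = 0.00145), but at 0.67 with each library's length and GC trend removed (adjusted p = 0.120).

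Astrocyte markers were higher in primary microglia in 13 of 14 and lower in 1 (median 9.74, or 6.197 at the bound, adjusted p = 1.93e-08, and adjusted p = 0.117 with an estimated correlation). Fibroblast markers were higher in 12 of 12 (9.05, or 5.51 at the bound, adjusted p = 0.00106, and adjusted p = 0.299 with an estimated correlation), and oligodendrocyte lineage markers in 10 of 10 (6.54, or 5.23 at the bound, adjusted p = 4.81e-04, and adjusted p = 0.0526 with an estimated correlation). Neuron markers were higher in 7 of 7 (8.78, or 5.25 at the bound, adjusted p = 0.00115, and adjusted p = 0.0629 with an estimated correlation). LXR targets were higher in 10 of 15 and lower in 2 (median 1.70, adjusted p = 1.69e-04, and adjusted p = 0.0739 with an estimated correlation), with Abca1 at 915 ± 18.3 against 32.3 ± 2.91 CPM. Glycolysis genes were lower in 14 of 20 and higher in 3 (median -1.31, adjusted p = 1.34e-06, and adjusted p = 0.0739 with an estimated correlation), with the lactate dehydrogenase gene Ldha at 254 ± 16.1 against 2319.6 ± 142 CPM. Alternative activation genes were higher in 10 of 14 and lower in 1 (median 1.49, adjusted p = 0.0229, and adjusted p = 0.186 with an estimated correlation). Phagocytosis genes were higher in 16 of 25 and lower in 5 (median 1.63, or 0.87 at the bound, adjusted p = 0.0117, and adjusted p = 0.115 with an estimated correlation).

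The lists below were not called between the cells with all libraries and unchanged processing. Interferon-stimulated genes were higher in 15 of 48 and lower in 10, or 14 and 10 over the list alone (median 0.42, or 0.32 at the bound, adjusted p = 0.946), and chemokines higher in 6 of 20 and lower in 7 (0.00, or -0.35 at the bound, 0.508). Ccl2 and Tnf were lower in primary microglia (log2 difference -4.76 ± 0.25 and -2.67 ± 0.23), Il1b was at -0.05 ± 0.39 (adjusted p = 0.931) and Irf1 at -0.29 ± 0.20 (0.201), and Irf8 and Arg1 were higher (1.30 ± 0.16 and 1.69 ± 0.45). Cytokines were higher in 9 of 24 and lower in 3, or 8 and 3 over the list alone (median 0.57, or 0.23 at the bound, 0.754), NF-kB pathway genes in 17 and 8 of 34 (0.50, 0.774), Toll-like receptor pathway genes in 11 and 7 of 27 (0.55, 0.508), IRF and STAT factors in 6 and 3 of 13 (0.64, 0.738) and classical activation genes in 11 and 5 of 21 (1.94, or 1.10 at the bound, 0.244). Antigen presentation genes were higher in 6 of 18 and lower in 9, or 7 and 9 over the list alone (median -0.41, 0.508), inflammasome genes in 6 and 6 of 19 (0.12, 0.946), complement genes in 10 and 3 of 15 (1.49, 0.0690), disease-associated microglia genes in 13 and 8 of 26 (0.37, 0.137) and immediate early genes in 12 and 2 of 18 (1.44, 0.0505). Without PM_EPZ replicate 2 the complement and immediate early lists passed (adjusted p = 0.0351 and 0.0335). With the replicate number as a block, the camera adjusted p of the immediate early list was 0.0379. It was 0.0454 in a fit of the 5 libraries without LPS and 0.0203 with no low-count filter. The immediate early list also passed without PM_EPZ_LPS replicate 1 (0.0461), PM_EPZ_LPS replicate 3 (0.0479) or BV2_EPZ replicate 1 (0.0460). PRC1 subunits were higher in 6 of 19 and lower in 4, or 5 and 4 over the list alone (median 0.04, 0.946), developmental regulators in 9 and 2 of 12 (4.21, or 3.92 at the bound, 0.180), cholesterol synthesis genes in 4 and 8 of 21 (-0.23, 0.410), NRF2 targets in 10 and 4 of 18 (0.59, 0.135), stress response genes of the unfolded protein pathway in 7 and 9 of 18 (-0.33, 0.243) and heat shock genes in 4 and 5 of 10 (-0.42, 0.205). With each library's length and GC trend removed, adjusted p was 0.00360 for complement genes, 0.00125 for disease-associated microglia genes, 0.00310 for NRF2 targets and 0.0124 for immediate early genes. Endothelial and mural markers were higher in 4 of 6 and lower in 1, or 4 and 2 over the list alone (median 5.41, 0.159).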

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

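The tests of a higher share of other brain cells, of a low yield in PM_EPZ_LPS replicates 2 and 3, of a level already high in BV2 cells, of the cell type and of the genes that lost their call were chosen after the result was seen.

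In primary microglia and BV2 cells 1418 genes differed in their response to LPS by a test of the difference. Members with a larger response in primary microglia numbered 8 of 20 chemokines, 34 of 48 interferon-stimulated genes, 16 of 34 NF-kB pathway genes, 8 of 13 IRF and STAT factors, 17 of 18 antigen presentation genes, 9 of 19 inflammasome genes, 6 of 15 complement genes, 9 of 20 glycolysis genes and 9 of 18 NRF2 targets, and 0 members of these lists had a smaller response with p-values adjusted over all genes. Over the list alone, 1 chemokine, 1 NF-kB pathway gene and 1 inflammasome gene had one. In other lists both kinds occurred, with 7 larger and 1 smaller of 24 cytokines, 8 and 1 of 27 Toll-like receptor pathway genes, 11 and 4 of 21 classical activation genes and 6 and 6 of 25 phagocytosis genes. A level already high in BV2 cells without LPS was weighed only for interferon-stimulated genes. Among the 1418 genes were 11 called with opposite signs in the cells. Differences of log2 fold changes were 4.00 for the Fc receptor gene Fcgr1, 3.06 for Rin2, 2.95 for Irf2, 2.70 for Tnfrsf11a, 2.53 for Ehd4, 1.87 for Maml2, 1.5001 for Dab2 and 1.31 for Ahnak, all higher in primary microglia. They were -3.31 for Fam46c, -1.88 for Fam20c and -1.45 for Cyb561a3. The opposite calls held on leaving out each library in turn for Dab2, Rin2, Fam46c and Fam20c, 4 of the 11. In BV2 cells without BV2_EPZ replicate 1, adjusted p was 0.453 for Ahnak, 0.299 for Cyb561a3, 0.207 for Ehd4, 0.331 for Fcgr1, 0.0519 for Irf2 and 0.0846 for Maml2. Without BV2_EPZ replicate 2 it was 0.113 for Tnfrsf11a, 0.171 for Ahnak, 0.101 for Cyb561a3, 0.0861 for Ehd4, 0.0593 for Irf2 and 0.0532 for Maml2. It was 0.0741 for Cyb561a3 without BV2_EPZ_LPS replicate 1 and 0.0880 for Irf2 without BV2_EPZ_LPS replicate 2. In primary microglia the calls lost were Tnfrsf11a without PM_EPZ replicate 3 (0.0592) and Cyb561a3 without PM_EPZ replicate 2 (0.0753) or 3 (0.153) or PM_EPZ_LPS replicate 2 (0.0920) or 3 (0.0561).

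The first pattern weighed was the smaller number of interferon-stimulated genes called in BV2 cells. Fewer libraries and depth were weighed in primary microglia with 2 libraries per group. Each library was thinned to at most 1611490 counts (the lowest BV2 total outside 6 structural RNAs, a set other than the 5 genes left out of the depths in the report). Primary libraries without LPS held 1299960, 1194800 and 1412490 such counts and were not thinned. BV2 libraries without LPS held 1747790 and 1611490, so their depth was not lower than that of the primary controls. With LPS, primary libraries held 1757660, 2146250 and 2439670 and BV2 libraries 1648740 and 1947990. In this test 100% of the tested genes (48 of 48) were called in each of 9 choices of libraries. Changes of the primary size (median 6.84 on the log2 scale) would thus have been called. The test cannot say whether smaller changes were missed in BV2 cells. There the median was 1.41, and 13 of 25 tested genes were called, or 17 adjusted over the list alone. A level already high in BV2 cells is argued against: with LPS the median difference, primary microglia minus BV2 cells, was 6.25 on the log2 scale, and medians without LPS were 1.91 and 1.28 CPM. The kind of cell, for which 34 genes had a larger response, cannot be told apart from strain, age and culture, which go with it in the design. By the test of the difference, interferon-stimulated genes responded less to LPS in BV2 cells under the inhibitor. Of 48 genes, 34 had a larger response in primary microglia and 0 a smaller one (camera adjusted p = 0.00403 with an estimated correlation). The reason is left open.

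The second pattern was the 1893 genes lower with LPS in primary microglia, which had longer transcripts. Falls in BV2 cells had longer transcripts as well (median 4304 bases, against 3137 for rises and 3421 for genes not called). The slopes of BV2 libraries on length lay between -0.017 and 0.040 per length doubling. In primary microglia, length and GC bias between libraries is argued against as the whole cause. Of the 1893 genes, 78.5% (1486) kept their call with each library's trend removed, and the median log2 fold change over all 1893 went from -0.96 to -0.84. Another 398 genes were called lower only with the trend removed. For the 407 genes that lost their call, the median went from -0.67 to -0.37, and bias cannot be told apart from a smaller true change. Without PM_EPZ_LPS replicate 1, 2 or 3, genes called lower numbered 2561, 1604 and 1442, so the count depended on the library. A low yield of long transcripts in PM_EPZ_LPS replicates 2 and 3 alone would be a trend on length as well. The same 78.5% is no separate test of it, because the rule that used this share was chosen after the result was seen. PM_EPZ_LPS replicate 1 was also set against a control left out of the selection (replicates 1, 2 and 3 in turn). Its medians were -0.64, -0.64 and -0.43, with 88.4%, 87.7% and 72.1% of the genes below the control. The last control missed the bound of -0.5 and the bound on the share, so this test did not decide and the low yield stays open. Against the same controls PM_EPZ_LPS replicates 2 and 3 had medians of -1.03, -1.05 and -0.78. A higher share of other brain cells with LPS would raise their markers. Markers below 0 were 11 of 14 for astrocytes (78.6%), 7 of 10 for oligodendrocytes, 8 of 11 for fibroblasts and 2 of 7 for neurons. Only the neuron markers thus leaned the way a higher share would push them. The sign test adjusted p was 0.229, 0.688, 0.680 and 0.688, so no list went beyond chance and the explanation stays open too.

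The third pattern was the presence of markers of other brain cells in the primary cultures. Within groups, astrocyte markers deviated together with a mean pairwise correlation of 0.367 (99.9th percentile of 1000 random lists) and fibroblast markers with 0.3297 (99.9th percentile), which is consistent with RNA of both kinds of cells in the cultures in amounts that varied by library. Oligodendrocyte and neuron markers lay at the 34.3rd and 60.9th percentile. No biological explanation was tested.

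For the 4178 genes changed by LPS in primary microglia, the 6 libraries allow too few splits (10) for a share under 0.05, and the highest count of another split was 0. One such split set PM_EPZ replicates 1 and 2 and PM_EPZ_LPS replicate 1 against the rest. It gave 774 genes at an unadjusted p under 0.05 in the edgeR test, and the remaining false splits gave 41 to 142. Reads on the other strand, which the comparisons did not use, made up 0.946%, 2.21% and 1.10% of stranded gene reads in the primary libraries with LPS, above the 0.682% to 0.826% of those without LPS.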

How the results depend on the processing

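Removing the length and GC trend and keeping a single primary library with LPS were chosen after the result was seen. Over the named genes, 3100 of 3213 values in primary microglia, 1927 of 2015 in BV2 cells, 3264 of 3379 differences of responses and 3986 of 4052 between the cells kept their direction and side of the threshold, with sign changes between values that did not pass on either side not counted. For the list tests it was 449 of 465, 286 of 300, 540 of 558 and 520 of 558. Leaving out single libraries gave 3322 to 5326 genes in primary microglia, 1002 to 1924 differences of responses, 7841 to 8969 between the cells and a correlation of responses of 0.564 to 0.644. Where 1 library was left in a group, its spread was taken from the other groups. Depth limits calls on genes near 1 CPM. The cause was not tested for any value that follows.

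In BV2 cells 318 genes were called by DESeq2, 774 with the length and GC trend removed, 353 without BV2_EPZ replicate 1 and 800 without BV2_EPZ_LPS replicate 1, against 485. The correlation of responses was 0.367 with no low-count filter, against 0.646. With the replicate number as a block, 4479 genes in primary microglia, 596 in BV2 cells and 1685 differences were called. List calls under the block numbered 12 for the difference of responses, against 13. Between the cells they stayed at 11, with 1 call lost and 1 gained.

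With an estimated correlation between genes, 7 lists were called in primary microglia, 3 in BV2 cells, 7 for the difference and 3 between the cells. Between the cells 15 lists were called with the length and GC trend removed and 13 without PM_EPZ replicate 2, against 11. The fry tests ask whether a list changed at all, not whether it ranked above or below the other genes, so they answer another question than the calls above. The directional fry test called 22 lists in primary microglia and 28 between the cells. The mixed fry test called 29, 20, 22 and 31. By directional fry the PRC1 subunits in primary microglia pointed up (adjusted p = 0.00447), where the test against the other genes pointed down without a call.

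With the length and GC trend removed, Abca9 was at -0.34, Kdm6a at -0.44, Slc7a2 at -0.69 and Tnfaip3 at -0.52 between the cells, each reversed, and over all genes 103 calls were opposite and 84.6% of the 8611 were kept. With PM_EPZ_LPS replicate 1 as the only primary library with LPS, Acta2 was at -0.49 and Gfap at -0.53. With all libraries each lay above 0 without a call.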

Other observations

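The tests of neighbouring genes were chosen before the result was seen.

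Some members of the lists in BV2 cells have not been described above. Slc7a11, the cystine transporter gene, rose from 12.0 ± 0.328 to 147 ± 29.7 CPM (log2 fold change 3.62 ± 0.21), and Nlrp3, the inflammasome sensor, from 24.5 ± 1.12 to 158 ± 6.34 CPM (2.69 ± 0.16). The receptor gene Gpr84 rose by 3.23 ± 0.28, the complement gene C3 by 1.802 ± 0.20, Mmp13 by 3.33 ± 0.55 and the transcription factor gene Spi1 by 0.76 ± 0.13 (n = 2 per group). In primary microglia the PRC2 accessory gene Phf1 fell from 12.7 ± 3.07 to 4.69 ± 0.446 CPM (adjusted p = 3.05e-04) and the PRC1 gene Kdm2b from 13.4 ± 2.80 to 5.21 ± 0.563 CPM, while Phc2 rose from 36.3 ± 3.89 to 90.7 ± 8.69 CPM. Atp6v0d2, a proton pump subunit, fell from 94.7 ± 4.63 to 24.3 ± 2.12 CPM, and Hspa5, a chaperone of the endoplasmic reticulum, rose from 148 ± 15.6 to 352 ± 16.0 CPM (n = 3 per group).

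Genes raised at least 2-fold by LPS lay next to each other on the chromosome more often than when calls were permuted. Neighbours with different name stems formed 192 pairs in primary microglia (permuted mean 109, highest of 1000 permutations 147) and 18 in BV2 cells (mean 7.20, highest 17). Another 78 pairs in primary microglia shared a name stem and were counted separately.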
